A study of Homo sapiens with 6 samples.

How the data were processed

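Messenger RNA was measured in 6 libraries of neurons derived from the human stem cell line iP11N, 3 from high density and 3 from low density wells. Per the labels' protocols, total RNA was extracted on day 28 and stranded libraries enriched for mRNA were made from 100 to 1000 ng of it. The authors deposited raw read counts per Ensembl gene, with no normalization, and the columns hold whole numbers with different totals. Per the submitters' processing notes, GSNAP was used with the genome build GRCh38. The version of GSNAP, the counting program, the annotation release, the treatment of reads that map to several places and the strand setting were not given in the sources used here. Where genes overlap or have near-identical copies, their counts are therefore uncertain. Columns were assigned to libraries by matching their names to the sample descriptions in the labels.

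The deposited counts covered 58302 genes, of which 41302 had a count in at least 1 library. Symbols were found for 42343 identifiers, and 58039 identifiers were in GENCODE release 29, which gave coordinates, gene types and exons on GRCh38. Total counts ranged from 14982300 to 22475400 per library. At a common biological coefficient of variation of 2.37%, differences well below 1.5-fold could be called, and genes under 1 CPM were measured with little precision. Levels are CPM scaled by TMM factors.

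The groups were compared with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test with robust dispersion, TMM scaling, group as the only term, and genes kept by filterByExpr (minimum count 10, minimum total 15). This left 18296 genes, of which 13862 were protein coding. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Log2 fold changes are high minus low density, and the standard error of a gene was taken as the absolute log2 fold change divided by the square root of the F statistic. The standard error of a mean or median over a set of genes was taken over its members, as if these were independent. It does not measure the spread between libraries. That of a share of counts or a summed level was taken over libraries. The count of genes changed at least 2-fold is a size filter on these calls and not a test of that fold. Single values per library were compared with exact permutation tests.

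Gene lists (36, of which 34 had at least 5 tested members) were fixed before the data were examined and tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The rule for named genes, also fixed before the data were examined, took the 12 largest rises and the 12 deepest falls among genes with adjusted p under 0.05, an average log2 CPM of at least 1, no overlap between groups and an approved-style symbol. It added up to 3 members with the smallest p from each list, or the member with the highest expression where none passed, and 8 identity genes. Other genes are said to have been chosen after their values were seen. Some genes that the rule selects are not reported here by name. XIST and Y-linked genes stayed in the tests and in the counts of genes, but were left out of the genes given by name and of the groups formed by symbol.

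Alternatives were RLE, upper-quartile and library-size-only scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a mean of at least 1 CPM, non-robust dispersion, removal of mitochondrially encoded genes, the replicate number as a block, and each library left out in turn. Removal of trends in transcript GC content and length was added after seeing the data.

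The procedures were tested on simulated data for the comparison of high with low density, with 200 genes changed. Counts followed the means, library sizes and trended dispersions of these libraries. Each gene thus had the dispersion of the trend at its level, and the rates do not cover genes that vary more than the trend. Counts were drawn for 18296 genes, of which 17949 passed the filter and were tested, and the percentages are of the genes drawn, with those filtered out counted as not called. EdgeR called 64.2% of the 67 genes changed 1.2-fold, 98.5% of the 67 changed 1.5-fold and 100% of the 66 changed 2-fold, and 0.0553% of the 18096 unchanged genes. The changed genes were drawn only from those with a mean of at least 5 CPM. The rates of detection therefore do not cover genes below that, which include HK2 and CRHBP, named below. Camera called the 1 list that was changed, with all its members lowered 1.2-fold, and 0 of the other 33. Genes were drawn independently of each other, so this cannot show whether the preset correlation limits false list calls where genes vary together.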

Results

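Gene expression was measured by RNA sequencing in neurons made from the human induced pluripotent stem cell line iP11N, with no genetic change according to its genotype label. Expression of the proneural transcription factor NGN2 (gene symbol NEUROG2) was switched on with doxycycline for 5 days, which turns stem cells into neurons, and the cells were matured until day 28. The series asks how the density of the cells in the wells affects the transcriptome. Of the 6 libraries, 3 came from high density wells and 3 from low density wells, and the design text of the series calls the latter group regular density. The number of cells per well was not given in the sources used here. Total counts were 16321100, 17393800 and 21908000 in low density replicates 1 to 3 and 14982300, 22475400 and 19812800 in high density replicates 1 to 3, rounded to 6 digits. The totals of the groups overlapped (exact permutation test, two-sided p = 0.9). The labels call the libraries repeats without saying whether they came from separate differentiations, so the p-values measure the spread between these libraries, which may be technical.

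The libraries separated by density along the first principal component of log2 CPM, a library-size-scaled count, which held 32.7% of the variance. Pearson correlations across genes were 0.9926 to 0.9933 between libraries of the same density and 0.9900 to 0.9917 between densities. The chi-square statistic per degree of freedom, which would be about 1 for sampling noise alone, ranged from 1.42 to 2.38 within groups and from 5.04 to 8.01 between them. No pair of libraries was so close that it had to be counted as 1 sample.

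High density neurons had higher mRNA levels of 9 of 20 glycolysis genes and lower levels of 13 of 23 activity-regulated and 9 of 18 neuropeptide genes, with some members of each list moving the other way. These 3 lists passed camera with the preset correlation but not with an estimated one (adjusted p = 0.49, 0.124 and 0.124). The largest rise among the genes selected by the fixed rule was in HK2 (ENSG00000159399, chromosome 2, 74833981 to 74893359, GRCh38), which encodes a hexokinase, the enzyme class that starts glycolysis. It measured 4.32 ± 1.89 CPM (SD, n = 3) at high density and 0.787 ± 0.122 CPM (SD, n = 3) at low density, a log2 fold change of 2.37 (SE 0.284, edgeR adjusted p = 1.06e-07). The deepest fall was in CRHBP (ENSG00000145708, chromosome 5, 76952713 to 76981158), which encodes a binding protein of corticotropin-releasing hormone. It measured 1.06 ± 0.119 CPM against 3.66 ± 0.261 CPM, a log2 fold change of -1.77 (SE 0.218, edgeR adjusted p = 1.97e-09). The smallest p belonged to SEMA3E (ENSG00000170381, chromosome 7, 83363238 to 83649113), a secreted semaphorin of axon guidance, with 113 ± 4.97 CPM against 242 ± 5.35 CPM, a log2 fold change of -1.10 (SE 0.0301, edgeR adjusted p = 1.21e-39).

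Of 18296 genes tested with edgeR's quasi-likelihood test, 2732 passed an adjusted p of 0.05, with 1324 higher and 1408 lower at high density, and 4727 had an unadjusted p under 0.05. Most differences were small. The median fold of the changed genes was 1.15, and 2410 of them (88.2%) differed by less than 1.5-fold. A further 224 lay between 1.5-fold and 2-fold, and 98 differed at least 2-fold, 57 of them higher and 41 lower. Fewer genes differed at least 2-fold when a mean of at least 1 CPM was required, as given below. The CPM values of the densities did not overlap for 5292 tested genes (28.9%, where chance gives 10%) and for 2605 of the changed ones. DESeq2 called fewer genes, 1564, of which 723 were higher, 841 lower and 31 changed at least 2-fold. With library size as the only scaling, 60.7% of the calls were higher, against 48.5% with TMM scaling.

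Only those genes selected by the rule that had an average log2 CPM of at least 1 are ranked here. Behind HK2, the ones that rose most were TAFA4, a secreted chemokine-like protein of sensory neurons (log2 fold change 1.604, SE 0.123), and TXNIP, the glucose-responsive inhibitor of thioredoxin (1.36, SE 0.181). TXNIP measured 87.4 ± 16.4 CPM (SD, n = 3) at high density and 34.1 ± 2.68 CPM (SD, n = 3) at low density (edgeR adjusted p = 0.0113). Its call was lost without low density replicate 1 (adjusted p = 0.0584), replicate 2 (0.0579) or replicate 3 (0.0554), within a range of 6.27e-48 to 0.0584 over its alternatives. The other 9 genes of the rising group had log2 fold changes of 1.03 to 1.35. They were AZGP1, PRIMA1, which anchors acetylcholinesterase to membranes, TRHR, the receptor of thyrotropin-releasing hormone, SHROOM4, SULT1C4, GPRC5A, STXBP2, ANGPT1, a ligand of the TIE2 receptor, and KLF10, a zinc finger transcription factor.

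Under the same limit, the genes that fell most after CRHBP included the neuropeptide genes SPX (log2 fold change -1.49, SE 0.207), CARTPT (-1.44, SE 0.184) and NTS, which encodes neurotensin (-1.07, SE 0.0398). NTS was at 127 ± 10.6 CPM (SD, n = 3) at high density and 268 ± 6.41 CPM (SD, n = 3) at low density. STC1, a secreted glycoprotein, fell from 107 ± 3.26 to 43.0 ± 2.08 CPM (log2 fold change -1.31, SE 0.0429, edgeR adjusted p = 1.94e-35). GALR1, a receptor of the neuropeptide galanin, fell by 1.10 on the log2 scale, and GABRE, a subunit of the GABA-A receptor, fell by 1.18. The remaining genes of this group were TPBG (-1.12), GPR50 (-1.10), TNFRSF9 (-1.04) and PLA2G7 (-1.03). SPX shares exon sequence on the opposite strand with GYS2, PLA2G7 with TDRD6 and STXBP2 with an unnamed gene, and since the strand setting of the counting was not given, these 3 values are uncertain.

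**Figure D1:**
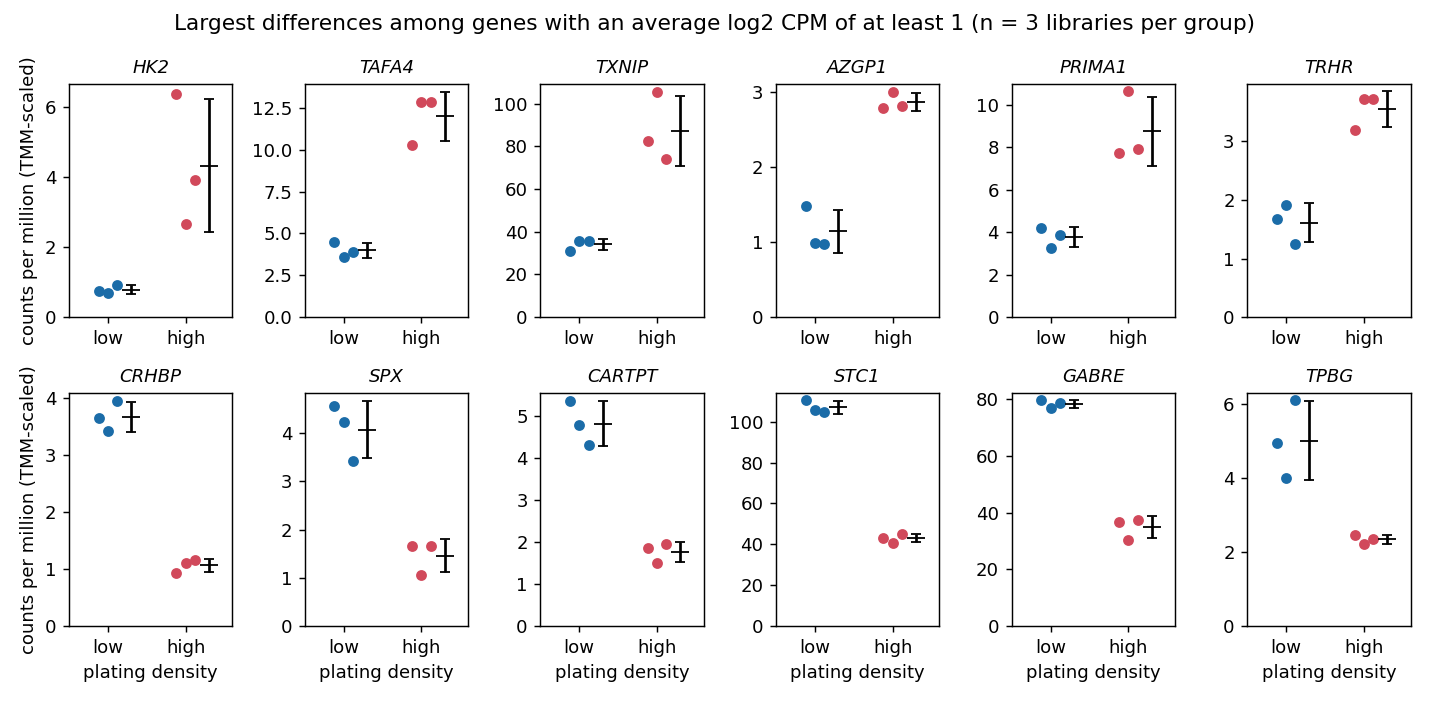
CPM (TMM-scaled, vertical axes starting at 0) of the 6 genes with the largest rise (top) and the 6 with the deepest fall (bottom) among those selected by the fixed rule with an average log2 CPM of at least 1, in the low density (blue) and high density (red) libraries. Points are libraries, the black dash is the mean and the bars are 1 SD (n = 3), and in each panel the groups do not overlap, as for HK2 at 4.32 ± 1.89 against 0.787 ± 0.122.

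Genes that neurons switch on with electrical activity were lower at high density. Of 23 tested members of the activity-regulated list, 13 fell, 1 rose and 9 did not pass the test (14 fell and 1 rose when adjusted over the list alone), and the list passed camera with an adjusted p of 1.07e-05. With an estimated correlation between genes the call was lost (adjusted p = 0.124). The AP-1 subunit gene FOSL2 went from 66.6 ± 1.49 CPM (SD, n = 3) at low density to 37.9 ± 1.57 CPM (SD, n = 3) at high density (log2 fold change -0.81, SE 0.0481). FOS fell by 0.59 and the MAP kinase phosphatase gene DUSP4 by 0.23 on the log2 scale. BDNF, singled out after its values were seen, encodes a growth factor of neurons and fell by 1.0005 (SE 0.0596).

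Neuropeptide and neurotrophic factor genes were also lower, with 9 of 18 members down, 2 up and 7 not passing (10 down and 3 up when adjusted over the list alone). BDNF, VGF and SCG2 belong both to this list and to the activity-regulated one, so the falls of these lists are not independent. The list passed camera (adjusted p = 0.0003), but not with an estimated correlation (adjusted p = 0.124). ADCYAP1, which encodes the neuropeptide PACAP, fell by 0.60 (SE 0.0275), although part of its exons lies opposite another annotated gene. The secretogranin gene SCG2, which also belongs to the activity-regulated list, fell by 0.47, from 2778 ± 70.3 to 2001 ± 88.8 CPM (SD, n = 3 each). FGF13 fell by 0.27.

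Lysosomal and cholesterol genes shifted down by small amounts. In the lysosome and autophagy list 13 of 21 members fell, 0 rose and 8 did not pass (the same counts when adjusted over the list alone), with a camera adjusted p of 1.07e-05 and an adjusted p of 0.124 with an estimated correlation. ATP6V1A, a subunit of the proton pump of lysosomes and vesicles, fell by 0.12, and the lysosomal proteases CTSD and TPP1 each fell by 0.28. Of 23 cholesterol genes 11 fell, 0 rose and 12 did not pass (12 fell and 0 rose when adjusted over the list alone), with a camera adjusted p of 1.07e-05 and an adjusted p of 0.203 with an estimated correlation. STARD4, a sterol carrier, fell by 0.34, ACAT2 by 0.29 and CYP51A1, an enzyme of sterol synthesis, by 0.20, where STARD4 and ACAT2 overlap genes on the opposite strand.

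Nuclear genes of oxidative phosphorylation were slightly lower as a list, although few passed one by one. Of 26 members 4 fell, 0 rose and 22 did not pass with edgeR (the same counts when adjusted over the list alone). Limma-voom called 2 members lower and DESeq2 called 1, with 0 higher for each. The list had a camera adjusted p of 0.00129 and an adjusted p of 0.124 with an estimated correlation. COX6C fell by 0.17, ATP5MC1 by 0.24 and NDUFV1 by 0.14. All 3 lost their call when certain single libraries were left out. COX6C then ran from -0.213 (without high density replicate 1) to -0.082 (without high density replicate 3). The share of counts on mitochondrially encoded genes was 4.56 ± 0.0508% (SD, n = 3) at high density and 5.39 ± 0.0776% (SD, n = 3) at low density, with no overlap (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 libraries can give). Of the 13 mitochondrially encoded protein genes 10 fell and 0 rose, with a median log2 fold change of -0.25. MT-CO2 and MT-ATP6, singled out after their values were seen, fell by 0.42 and 0.38. Of 17 tested nuclear pseudogene copies of these genes, MTND2P28, MTATP6P1 and MTND4P12 fell (log2 fold changes -0.27, -0.31 and -0.27), 0 rose and 14 did not pass with edgeR (0 higher and 4 lower at an unadjusted p under 0.05, 0 higher and 3 lower with limma-voom, 0 higher and 2 lower with DESeq2). How reads that match both a copy and its mitochondrial gene were counted was not given, which leaves these values uncertain.

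Presynaptic genes were lower by small amounts. Of 22 members 11 fell, 2 rose and 9 did not pass (the same counts when adjusted over the list alone). The list passed camera (adjusted p = 0.0196), but not with an estimated correlation (adjusted p = 0.329), with library size as the only scaling (0.0542), without low density replicate 3 (0.0612) or without high density replicate 1 (0.0667). Its adjusted p ranged from 0.00942 to 0.329 over the camera alternatives. The vesicle protein gene SV2B fell by 0.24 and the vesicle priming gene UNC13A by 0.15.

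Glycolysis genes were higher at high density. Of 20 members 9 rose, 2 fell and 9 did not pass (10 rose and 2 fell when adjusted over the list alone), with a camera adjusted p of 0.000454 and an adjusted p of 0.49 with an estimated correlation. Besides HK2, the lactate dehydrogenase gene LDHA rose from 79.4 ± 1.87 CPM (SD, n = 3) to 132.5 ± 12.9 CPM (SD, n = 3), a log2 fold change of 0.73 (SE 0.0516). ENO1 rose by 0.35 and PGK1 by 0.23. Members with pseudogenes named after them (LDHA, ENO1, PGK1 and HK2 among them) had a median log2 fold change of 0.20 (SE 0.0855, 10 genes), against 0.047 (SE 0.0394, 10 genes) for members without. The difference between these medians was within 2 standard errors, and how reads shared with such copies were counted was not given. PGK1 also overlaps ATP7A on the same strand.

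Hypoxia response genes were higher as a list. Of 20 members 6 rose, 3 fell and 11 did not pass (8 rose and 3 fell when adjusted over the list alone). VEGFA, an angiogenic growth factor, rose by 0.84 (SE 0.0744), the pyruvate dehydrogenase kinase gene PDK1 by 0.46 and the mitophagy receptor gene BNIP3L by 0.26, although BNIP3L overlaps PNMA2 on the opposite strand. The list passed camera (adjusted p = 0.0215), but not with an estimated correlation (adjusted p = 0.223), on ranks (0.0712), without high density replicate 1 (0.0845) or without low density replicate 2 (0.053). Its adjusted p ranged from 0.0117 to 0.223 over the camera alternatives.

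Markers of peripheral and sensory neurons were higher in 5 of 15 members and lower in 0, with 10 not passing (6 higher and 0 lower when adjusted over the list alone). NTRK3, the receptor of neurotrophin-3, rose by 0.84 (SE 0.0596), the ATP-gated channel gene P2RX3 by 0.57 and the receptor tyrosine kinase gene RET by 0.46. RET measured 388 ± 18.8 CPM (SD, n = 3) at high density and 283 ± 1.51 CPM (SD, n = 3) at low density. The list passed camera (adjusted p = 0.0197), but not with an estimated correlation (adjusted p = 0.531), on ranks (0.0921), without high density replicate 1 (0.0848) or without low density replicate 2 (0.079), within a range of 0.00333 to 0.531 over the camera alternatives.

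Neural progenitor markers were higher in 5 of 17 members and lower in 1, with 11 not passing (6 higher and 2 lower when adjusted over the list alone). SOX1 rose by 0.62 to 8.99 ± 1.38 CPM (SD, n = 3), NES, which encodes an intermediate filament of progenitors, by 0.14, and ID4 by 0.15. The camera adjusted p was 0.0295, and 0.231 with an estimated correlation. It was also above the threshold with a mean of at least 1 CPM per gene (0.183), with library size as the only scaling (0.0567), and without low density replicate 2 (0.053), low density replicate 3 (0.103) or high density replicate 1 (0.113), within a range of 0.01001 to 0.231 over the camera alternatives.

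**Figure D2:**
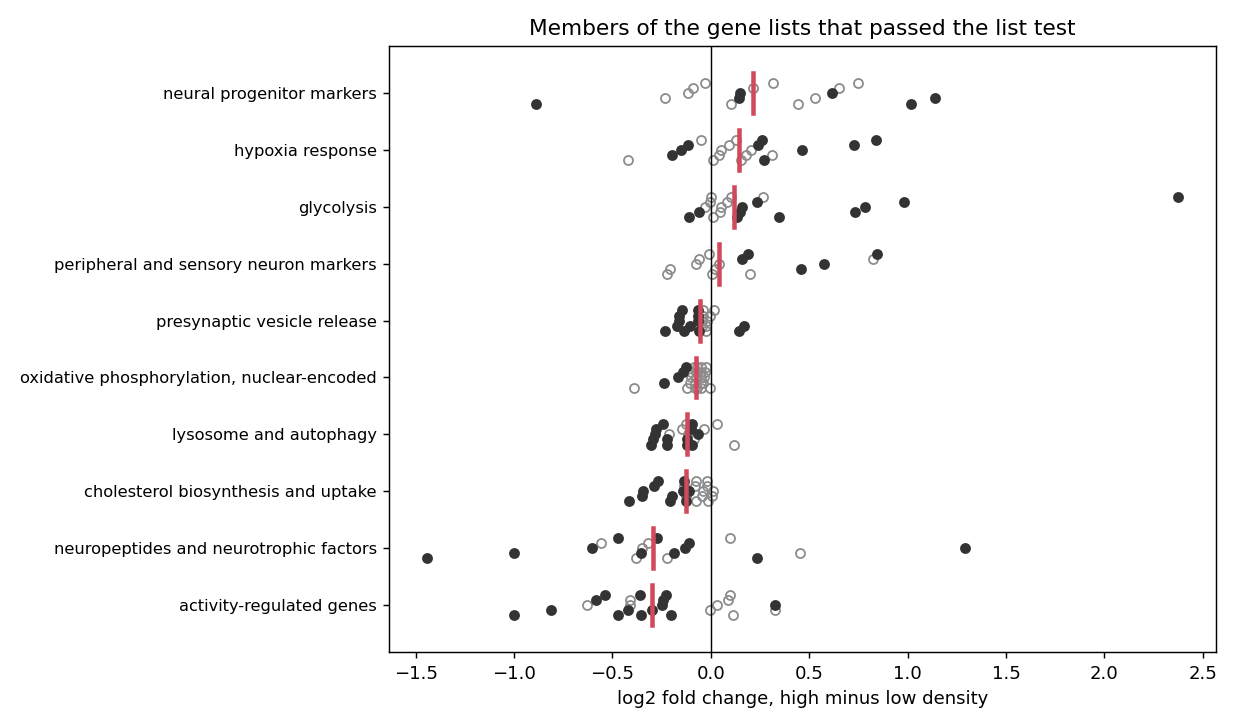
Log2 fold change (high minus low density, horizontal axis) of each tested member of the 10 gene lists that passed camera with the preset correlation, with 1 row per list. Filled points passed the adjusted p threshold of 0.05 over all genes, open points did not, the vertical offsets are for display only, and the red bar is the median, which lies at -0.30 for the activity-regulated list and at 0.12 for glycolysis.

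In all, 10 of the 34 lists tested passed camera with the preset correlation, 4 of them higher and 6 lower, and 0 passed camera with an estimated correlation (7 at an unadjusted p under 0.05). Without high density replicate 1, 6 lists passed. The self-contained test fry, which asks whether the members of a list move one way on balance without comparing them with other genes, passed 16 lists, and its mixed version passed 31.

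Several neuronal groups held genes that moved both ways. Among 25 postsynaptic glutamate receptor and scaffold genes 8 rose, 8 fell and 9 did not pass (the same counts when adjusted over the list alone, camera adjusted p = 0.497). The NMDA receptor subunit gene GRIN2B rose by 0.57 and the kainate receptor gene GRIK3 by 0.49, and the adhesion gene LRRTM2, which lies opposite CTNNA1, by 0.49. Of 29 axon guidance genes 10 rose and 8 fell (11 and 9 when adjusted over the list alone, adjusted p = 0.763), with SEMA6A down by 0.33 and EFNB2 at a log2 fold change of 0.35. Neural cell adhesion genes rose in 8 and fell in 5 of 25 cases (9 and 6 when adjusted over the list alone, adjusted p = 0.344), among them CDH12 at 0.60, PCDH19 at 0.56 and PCDH9 at -0.23. Voltage-gated channel genes rose in 2 and fell in 7 of 25 cases (6 and 9 when adjusted over the list alone, adjusted p = 0.344), and the potassium channel gene KCNA1 fell by 0.90 and CACNA1E by 0.23.

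The neuronal cytoskeleton list held 7 higher and 5 lower genes among 20 (7 and 6 when adjusted over the list alone, adjusted p = 0.763). The neurofilament genes NEFM and NEFL fell by 0.21 and 0.09, and MAP6 rose by 0.14. The glutamatergic identity list had 4 higher and 4 lower genes among 12 (the same when adjusted over the list alone, adjusted p = 0.91), with GRIN1 at 0.65, SLC1A2 at -0.18 and SLC17A6 at -0.13. The list of GABAergic, cholinergic and monoaminergic identity had 2 higher and 1 lower among 13 (2 and 2 when adjusted over the list alone, adjusted p = 0.654), with GAD2 at 0.997, DDC at 0.79 and SLC5A7 at -0.23. Of 16 axon injury genes 6 rose and 2 fell (6 and 3 when adjusted over the list alone, adjusted p = 0.344), with HRK at 0.73, JUN at 0.70 and DUSP16 at 0.28.

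The pluripotent stem cell list had 3 higher and 1 lower gene among 10 (4 and 1 when adjusted over the list alone, camera adjusted p = 0.0768), with DPPA4 at 1.83, EPCAM at 0.33 and LIN28B at -0.12, and DPPA4 stayed below 1 CPM in both groups on average. This list passed camera without high density replicate 3 (adjusted p = 0.0188) and without low density replicate 3 (0.0452), within a range of 0.0188 to 0.544 over the camera alternatives. The astrocyte list had 1 higher and 1 lower among 10 (the same when adjusted over the list alone, adjusted p = 0.497), namely ALDOC at 0.79 and GJA1, a gap junction gene at 0.517 ± 0.169 against 1.69 ± 0.406 CPM (SD, n = 3 each), at -1.66. The oligodendrocyte and Schwann list had 1 higher among 9, MBP at 0.25 (the same when adjusted over the list alone, adjusted p = 0.171), and the list passed without low density replicate 2 (0.0134). The mesenchymal list had 1 lower among 13, THY1 at -0.17 (the same when adjusted over the list alone, adjusted p = 0.763). The cell cycle list had 0 changed genes among 17 with edgeR, and likewise 0 with limma-voom and DESeq2 (2 higher and 1 lower at an unadjusted p under 0.05 with edgeR), where HMGB2 was at -0.03 (adjusted p = 0.838), and a camera adjusted p of 0.763. Of the microglia list only PTPRC was tested, at 0.41 (adjusted p = 0.203), and the metallothionein list had 3 tested members, with MT1F at -0.01 (adjusted p = 0.977), too few for camera.

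The ATF4 list had 6 higher and 2 lower genes among 24 (the same when adjusted over the list alone, adjusted p = 0.0572), with DDIT4 at 0.73, PHGDH at 0.35 and ATF5, which overlaps NUP62, at 0.34, and it passed without high density replicate 3 (0.022). The unfolded protein response list had 0 higher and 3 lower among 20 (the same when adjusted over the list alone, adjusted p = 0.0655), with PDIA3 and HYOU1 both at -0.13 and HSP90B1 at -0.08. The NRF2 list had 1 lower among 18, ME1 at -0.20 (adjusted p = 0.344), heat shock had 2 higher and 2 lower among 14, with HSPA4L at -0.21, HSP90AB1 at 0.08 and HSP90AA1 at 0.06 (adjusted p = 0.787), and p53 and apoptosis had 3 higher and 2 lower among 21, with HRK at 0.73, TP53INP1 at 0.32 and BBC3 at 0.76 (adjusted p = 0.819). Interferon had 1 lower among 12, IFI6 at -0.55 (adjusted p = 0.536). Adjusted over the list alone, these 4 lists gave 0 and 1, 3 and 2, 3 and 2, and 0 and 1 higher and lower genes.

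Wnt targets had 3 higher and 2 lower genes among 12 (5 and 3 when adjusted over the list alone, adjusted p = 0.385), with the cyclin gene CCND1 at 0.85, APCDD1 at 0.98 and BAMBI at 0.83, and CCND1 overlaps LTO1 on the opposite strand. Notch had 1 higher among 14, DTX1 at 0.14 (the same when adjusted over the list alone, adjusted p = 0.495). YAP and TAZ targets had 2 lower among 15 (the same when adjusted over the list alone, adjusted p = 0.593), with TEAD1 at -0.18 and NT5E at -0.93. The extracellular matrix list had 2 higher and 6 lower among 22 (the same when adjusted over the list alone, adjusted p = 0.451), with the integrin genes ITGA6 at -0.60, ITGA3 at -0.34 and ITGB1 at -0.20. Ribosomal proteins had 1 higher among 25, RPL5 at 0.16, which overlaps DIPK1A (the same when adjusted over the list alone, adjusted p = 0.171), and passed without high density replicate 3 (0.022). Genes named RPL or RPS held only 0.488% of counts at high and 0.476% at low density on average. How reads that map to several places were counted was not given, so the values of this list are uncertain. The median, the mean and the direction of the test differed in sign for the extracellular matrix, glutamatergic, axon guidance, heat shock and cytoskeleton lists, none of which passed.

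Identity genes were measured whatever their result. MAP2, a dendritic microtubule protein, was at 4651 ± 83.0 CPM (SD, n = 3) at high density and 4557 ± 68.2 CPM (SD, n = 3) at low density (edgeR adjusted p = 0.275). SYN1 was at 196 ± 2.08 and 202 ± 2.79 CPM (adjusted p = 0.341). SLC17A6, a vesicular glutamate transporter, fell by 0.13, from 1327 ± 5.595 to 1215 ± 20.8 CPM (SD, n = 3 each). NEUROG2 itself was at 1.40 ± 0.287 and 0.868 ± 0.10 CPM (adjusted p = 0.131). The pluripotency gene POU5F1 was at 11.1 ± 1.14 against 8.91 ± 0.822 CPM (log2 fold change 0.31, adjusted p = 0.0367), with adjusted p of 0.00792 to 0.209 over its alternatives, and it overlaps TCF19. GFAP, an astrocyte filament, stayed below 1 CPM on average in both groups (adjusted p = 0.262). TUBB3 was at 7.15 ± 0.791 and 8.97 ± 0.751 CPM (adjusted p = 0.055), and since its exons are shared with an annotated readthrough gene, its count is uncertain.

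Of the 108 named genes that passed, 13 lost their call under at least 1 alternative, and none turned direction where it was tested. Without low density replicate 1 the calls of HSP90AA1, BAMBI, RPL5, NT5E, ATP5MC1, COX6C, NDUFV1, LIN28B and POU5F1 were lost, besides that of TXNIP. Leaving out low density replicate 2 ended those of ME1, HSP90AA1, DPPA4, RPL5, DTX1, NT5E, COX6C, NDUFV1, LIN28B and POU5F1, and leaving out low density replicate 3 those of HSP90AA1, RPL5, ATP5MC1 and COX6C. Without high density replicate 1 the calls of ME1, DPPA4, RPL5, DTX1, NT5E, ATP5MC1, NDUFV1, LIN28B and POU5F1 were lost, without replicate 2 those of ME1, RPL5, DTX1, ATP5MC1 and POU5F1, and without replicate 3 those of HSP90AA1, NT5E, COX6C, NDUFV1 and LIN28B. Their highest adjusted p over all alternatives ranged from 0.0569 for DPPA4 to 0.305 for NT5E, with 0.257 for RPL5, 0.196 for NDUFV1 and 0.178 for COX6C.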

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

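The tests with GC content and length trends removed were chosen after the result was seen, and the other settings were fixed before the data were examined. The count of changed genes, 2732, stayed within 1.5 times under every setting except DESeq2 (1564 changed, 723 higher, 841 lower, 31 at least 2-fold, with 1560 of its calls shared and in the same direction). With a mean of at least 1 CPM, 45 genes changed at least 2-fold, since fewer genes were tested, and the first component held 38.9% of the variance, against 35.6% over the 500 most variable genes. The number of lists that passed was 0 with an estimated correlation and 16 with fry, and the cause was not tested for DESeq2 or fry. Leaving out 1 library gave 2077 to 2608 changed genes, 961 to 1313 higher, 1062 to 1295 lower, 80 to 121 changed at least 2-fold and 6 to 13 lists. The replicate numbers did not pair the libraries (correlations of deviations 0.010, -0.067 and -0.031 for equal numbers), and the fit with the number as a block gave 2718 changed genes (1308 genes higher at high density, 1410 genes lower at high density, 90 at least 2-fold) and 10 lists.

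Of 116 named genes 108 were called, and 95 of these kept their call under every setting that gave them an adjusted p, while 13 lost it in at least 1. DESeq2 gave one to 105 of the 108 (not to GJA1, DPPA4 or NT5E), and the setting with a mean of at least 1 CPM to 107 (not to DPPA4). None of the called genes reversed where tested. Reversals were among genes and lists that had not passed: MT1F was at 0.0065 with library size only and from -0.162 to 0.058 over left-out libraries, and HMGB2 ran from -0.088 to 0.027. For lists, the mean difference from other genes was -0.046 for interferon and 0.090 for glutamatergic identity at a mean of at least 1 CPM, 0.117 for glutamatergic identity on ranks, 0.0055 for axon guidance and -0.014 for p53 with fry, where the direction is that of the test. Over left-out libraries the list values ran from -0.022 to 0.015 for heat shock, -0.066 to 0.021 for p53, 0.097 to 0.192 for glutamatergic identity and 0.025 to 0.20 for mesenchymal markers; the cause was not tested.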

Other observations

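The grouping of genes by symbol and the tests with GC content and length trends removed, of neuron share, of proliferating cells, of pseudogenes and nuclear copies, and of the share of counts left by mitochondrial genes were chosen only after the result was seen. Among 223 groups of tested genes that share the start of their symbol (at least 8 members each), 5 passed camera with the preset correlation, and with an estimated correlation their adjusted p was 0.843 to 0.869. GABA-A and related receptor subunit genes were lower in 9 of 16 cases and higher in 0 (adjusted p = 5.39e-05). GABRQ fell by 0.75 (SE 0.0469), from 87.6 ± 1.81 to 52.0 ± 5.09 CPM (SD, n = 3 each), and GABRA3 by 0.25, while GABRA4 and GABRB1 overlap each other. Genes named ATP were lower in 22 of 75 cases and higher in 3 (adjusted p = 0.00277), and those that fell included the proton pump subunits ATP6V1C1 (-0.18), ATP6V0A1 (-0.14) and ATP6V1B2 (-0.14) and the sodium pump subunit ATP1B1 (-0.14).

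SOX transcription factor genes were higher in 6 of 13 cases and lower in 0 (adjusted p = 0.00277). SOX4, which is expressed in immature neurons, rose by 0.41 (SE 0.0211), from 494 ± 2.70 to 654 ± 13.0 CPM (SD, n = 3 each), and SOX11 by 0.09. Histone demethylase genes named KDM were higher in 7 of 17 cases and lower in 1 (adjusted p = 0.0155), with KDM3A at 0.27 and KDM5B at 0.21. PHF genes, which encode PHD finger proteins, were higher in 5 of 19 cases and lower in 0 (adjusted p = 0.0155).

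The real grouping of the libraries gave 2732 changed genes, 1324 higher, 1408 lower, 98 at least 2-fold and 10 lists. Among the other splits of the 6 libraries into 3 and 3, the highest counts were 0 genes with edgeR (at most 609 at an unadjusted p under 0.05) and 2 lists, so that 1 of the 10 splits, the real one, gave values as large. With 10 splits the share is never under 0.1, which is too few to test chance.

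The activity-regulated and neuropeptide lists were lower at high density with the preset correlation, but neither passed with an estimated one (adjusted p = 0.124 for each). With GC content and length trends removed, the pooled members of both lists stayed at a mean log2 fold change of -0.244 relative to other genes (SE 0.0731 over members). With the trends kept this mean was -0.241, and so small a change argues against those trends as the whole cause. A lower share of neurons would lower the genes that all neurons use by about as much. The neuronal cytoskeleton list, however, had a median of 0.0223 (SE 0.0277 over members), against -0.261 for both lists together, which argues against a lower share as the whole cause. Other rows go with fewer neurons, and a smaller drop stays open. Progenitor markers were higher in 5 and lower in 1 of 17 cases (SOX1 by 0.62, NES by 0.14). Presynaptic genes were lower in 11 and higher in 2 of 22 cases (median -0.053). Neither list passed camera with an estimated correlation (adjusted p = 0.231 and 0.329). SLC17A6, NEFM and NEFL fell by 0.13, 0.21 and 0.09. MAP2 and SYN1, however, did not pass the edgeR test, and 7 of 20 cytoskeleton genes rose while 5 fell. POU5F1 rose by 0.31, but not past the threshold without low density replicate 1 or 2 or high density replicate 1 or 2 (adjusted p = 0.203, 0.0622, 0.129 and 0.164). The call of POU5F1 was also lost with DESeq2, with limma-voom and with no filter on low counts. A candidate explanation that stays open is lower electrical or secretory activity per neuron at high density, which the libraries do not measure.

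The glycolysis list was higher at high density with the preset correlation, with 9 of 20 members higher and 2 lower, but it did not pass with an estimated one (adjusted p = 0.49). The list kept a mean of 0.297 (SE 0.127 over members) relative to other genes with GC and length trends removed. With the trends kept this mean was 0.303, and so small a change argues against those trends. Reads shared with pseudogenes cannot be told apart from a real rise, since the members with no pseudogene named after them had a median of 0.0472 (SE 0.0394) and only 3 of these 10 rose, against 6 of the 10 others. Outside the list, 234 genes with at least 5 named pseudogenes had a median of 0.0125 (SE 0.00813), so no general shift of such genes was seen. RNA from proliferating cells also stays open (cell cycle genes of at least 1 CPM had a median of 0.0231, SE 0.0388, against 0.118 for glycolysis), as does a biological response of the cells to crowding, such as lower oxygen. Oxygen was not measured, and of 20 hypoxia response genes 6 rose and 3 fell (camera adjusted p = 0.0215, but 0.223 with an estimated correlation, 0.0712 on ranks, 0.0845 without high density replicate 1 and 0.053 without low density replicate 2).

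Mitochondrially encoded mRNAs were lower at high density in 10 of 13 cases. The nuclear oxidative phosphorylation list passed camera as lower with the preset correlation, but not with an estimated one (adjusted p = 0.124). Of its 26 members 4 were lower with edgeR, 2 with limma-voom and 1 with DESeq2. With GC and length trends removed, the mitochondrial genes had a median log2 fold change of -0.255 (SE 0.023 over genes) and the nuclear list a mean of -0.106 (SE 0.0149 over members) relative to other genes. With the trends kept, the median was -0.253 and the mean -0.103. These values argue against those trends. The planned test of the scaling, the mean of the nuclear list relative to other genes without the mitochondrial genes (-0.103, SE 0.0154), cannot decide, since a change of scaling moves all genes alike. The test that replaced it, with the mitochondrial shares already known, took the log2 difference in the share of counts left to the other genes. That share was higher at high density by 0.0126 (SE 0.000814), a sign that follows from the known mitochondrial shares. With library size as the only scaling, it would raise the nuclear genes and not lower them. The fold changes given here use TMM scaling, however. With TMM scaling, the median of the nuclear list was -0.07678 with the mitochondrial genes and -0.07683 without them. Reads moved to nuclear copies would raise these, but the summed level of all 394 named copies differed by -241.2 CPM (SE 27.5), against a loss of 8970 CPM by the mitochondrial protein genes, which argues against it as the cause. Reads dropped because they match several places left no count to test. A lower mitochondrial content or transcription per cell at high density is a hypothesis that these libraries could not test.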
